A study of Homo sapiens with 2 samples.

How the data were processed

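Gene expression was measured on Affymetrix PrimeView arrays in HCT116 cells, a human colorectal carcinoma line. Each group held 1 array: cells with a scrambled hairpin (the control) and cells with a short hairpin RNA against SUN2 (the knockdown). Biotinylated cRNA was made from 100 ng of total RNA, per the labels' protocols.

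The deposited values were probe set intensities on a linear scale, as the authors submitted them to the repository. The submitters' processing notes name MAS5 and RMA, with no role or order for either, and the normalization between the arrays is not given in the sources used here. The lowest deposited intensity was 30.8 on the control array and 29.965 on the knockdown array. The median was 108.8 on the control array and 107.1 on the knockdown array. The background control probe sets, which match no human transcript and differ in their number of G and C bases, were not near 0. Their intensity on the control array ran from 31.7 at 3 G or C bases to 1425 at 25. Background was therefore still part of the values, and equal background on both arrays would make a fold understate a difference in transcript level, most of all for dim genes. Background was not equal, as 20 of the 23 background controls were lower in the knockdown array, so a decrease can also be overstated. Whether the values were centred or scaled to each other stays unknown. No detection call or probe-level value was used here.

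The table held 49395 probe sets. The 102 control probe sets were kept apart. Of the other 49293, the platform annotation gave 1 gene symbol to 44988, several to 1832 and none to 2473. Symbols were updated through the Entrez ID, which matched for 44961 of the 44988, in the RefSeq annotation of GRCh38.p14. No coordinates were taken from that annotation, since the build behind the array design was not given. Genes listed only through probe sets with several or no symbols were not analysed here.

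Values were put on the log2(intensity + 16) scale, and every difference is the knockdown array minus the control array on that scale. A gene was represented by its probe set with the highest mean over both arrays. Genes were kept when that mean was at or above the median of all probe sets without controls, an intensity of about 108. This left 12220 of 18132 genes. That cut lies between the background controls with 16 and 17 G or C bases, so a dim gene with GC-rich probes can still hold mostly background.

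With 1 array per group there are no replicates, no residual degrees of freedom and no test: no p-value, standard error or SD between cultures exists for any value. Genes are counted past a fixed size of 2-fold, with counts at 1.5-fold and 3-fold beside it. The only measure of error is the agreement between probe sets of a gene, which covers probe error within these arrays and nothing else. Probe sets of a gene may share probes, which was not checked and would make this error look too small. The number of arrays limits the precision.

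A total of 41 gene lists was fixed before the data were examined. Of their 840 genes, 770 had a probe set with 1 symbol and 650 passed the filter. Each list's median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins. A list was called outside the random range when it fell in the lowest or highest 2.5% of these. This percentile describes these 2 arrays and is not a p-value. Genes of a list are regulated together, so a list leaves the random range more readily than independent genes would.

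Genes were named by a rule set at the same time as the lists. It took SUN2, SUN1, BDNF and NTRK2, and up to 15 genes per direction past 2-fold whose probe sets past the filter all differed in the same direction. It also took the 4 members with the largest difference in each list that is described, and any list member past 2-fold. Genes between 1.5-fold and 2-fold were added by the same rule after the values were seen.

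The alternatives were median centring, quantile normalization, a loess correction of the difference on intensity, the mean of all probe sets of a gene, leaving out probe sets of the _x_at and _s_at classes, 3 other filters on low values and pseudocounts of 1 and 64. The mean of all probe sets also covers those below the filter, so dim probe sets can bring a difference closer to 0. A normexp background correction was added after the values were seen. The same gene and list steps were tested on simulated data made from the control array, with 200 genes changed and a probe noise SD of 0.1 on the log2 scale. With the 2-fold threshold, 25 of 25 genes raised 3-fold were recovered, and 17 of 25 genes lowered 3-fold. Of genes changed exactly 2-fold, 6 of 25 raised and 3 of 25 lowered genes were counted. No unchanged gene passed either 2-fold or 1.5-fold, at a noise that holds no variation between cultures. At 1.5-fold, 17 of the 25 genes lowered 3-fold were again counted, so the others were lost to the filter on low values and not to the threshold. Each simulated fold multiplied the whole intensity, background included, so recovery of changes in transcript level in the real arrays can be lower. In a simulation with no list raised, 0 of 41 lists left the range of 1000 random lists. In a second simulation with 3 lists raised by 0.15 on the log2 scale, those 3 did. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.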

Results

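The comparison addressed which transcripts lie downstream of SUN2, an inner nuclear membrane protein of the LINC complex that links the nucleus to the cytoskeleton. Expression was profiled in HCT116 cells carrying a scrambled hairpin or 1 hairpin against SUN2, with 1 array in each group. The intensities of the 2 arrays correlated with r = 0.995 across probe sets on the log2 scale. For genes past the filter on low values, the median difference between the arrays was -0.0009, with quartiles of -0.08 and 0.11. Probe sets of the same gene scattered around their gene's mean with an SD of 0.09 on the log2 scale, over 5786 genes with at least 2 probe sets. In 63.9% of these genes all probe sets differed in the same direction. No replicate exists for any value below, and each fold is on the log2(intensity + 16) scale.

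SUN2 itself was lower in the knockdown array, by a small amount. Its brightest probe set read 497.7 in the control array and 407.3 in the knockdown array, 81.8% of control, a log2 difference of -0.28 or 1.21-fold lower. All 4 SUN2 probe sets past the filter were lower, from -0.39 to -0.07. The difference was 2.96 times the SD of a probe set around its gene's mean, which covers probe error and no variation between cultures. That SD is too small if probe sets of a gene share probes. A total of 80 genes of the 12220 had a larger decrease than SUN2. SUN1, the other widely expressed SUN-domain protein, was higher by 0.22 on its 1 probe set past the filter and by 0.02 when its 5 probe sets were averaged.

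Few genes differed by 2-fold, and nearly all of them were higher in the knockdown array. Of 12220 genes, 9 were at least 2-fold higher and 1 was at least 2-fold lower. At 1.5-fold the counts were 41 higher and 3 lower, against 29 and 10 after quantile normalization and 32 and 8 after loess. At 3-fold they were 2 higher and 0 lower. Histone genes were among the highest: H1-2, a linker histone, was 3.67-fold higher (log2 difference 1.88), from an intensity of 105.2 to 428.6. As that control value lies in the range of the background controls, the size depends on the treatment of background: 1.54 with a pseudocount of 64, below H2BC12 (1.65), and 2.25 with normexp. The H2B genes H2BC12 and H2BC5 were 3.46-fold (1.79) and 2.18-fold (1.13) higher. H2BC12 was higher by 0.92 in log2 when its 2 probe sets were averaged, the second of which lies below the filter. PLK2, a polo-like kinase induced by stress, was 2.72-fold higher (1.44), and the hair keratin-associated gene KRTAP2-3 was 2.68-fold higher (1.42). The annexins ANXA10 and ANXA3 were 2.20-fold and 2.01-fold higher, and the interferon-induced gene IFI27 was 2.13-fold higher.

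BDNF, a neurotrophin and ligand of the TrkB receptor, was 2.03-fold higher (1.02), from an intensity of 397.8 to 824.5. All 5 of its probe sets were higher, by 0.59 to 1.02. NTRK2, which encodes that receptor, differed by 0.03 on the 1 of 10 probe sets that passed the filter, whose intensity of 107.4 lies close to the cut. MAPRE1, which encodes the microtubule plus-end protein EB1, was the only gene at least 2-fold lower, 2.06-fold (-1.05) on one probe set and with a log2 difference of -0.66 on the other. In the plot of single probe sets, BDNF, MAPRE1, ANXA3 and H2BC5 are supported by more than 1 probe set past the filter. PLK2 is not: its second probe set past the filter differed by 0.03. IFI27 differed by 0.42 on its second. H1-2, H2BC12, KRTAP2-3 and ANXA10 each rested on 1 probe set past the filter. Histone genes and KRTAP2-3 have near-identical copies, so their assignment to 1 gene is uncertain. Without probe sets of the _x_at and _s_at classes PLK2 stood at 0.03, and 5 genes were at least 2-fold higher. Averaging all probe sets of a gene left 4 genes at least 2-fold higher and 0 lower. After quantile normalization or loess 6 of the 9 higher genes stayed past 2-fold, without BDNF, ANXA3 and IFI27.

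**Figure D1:**
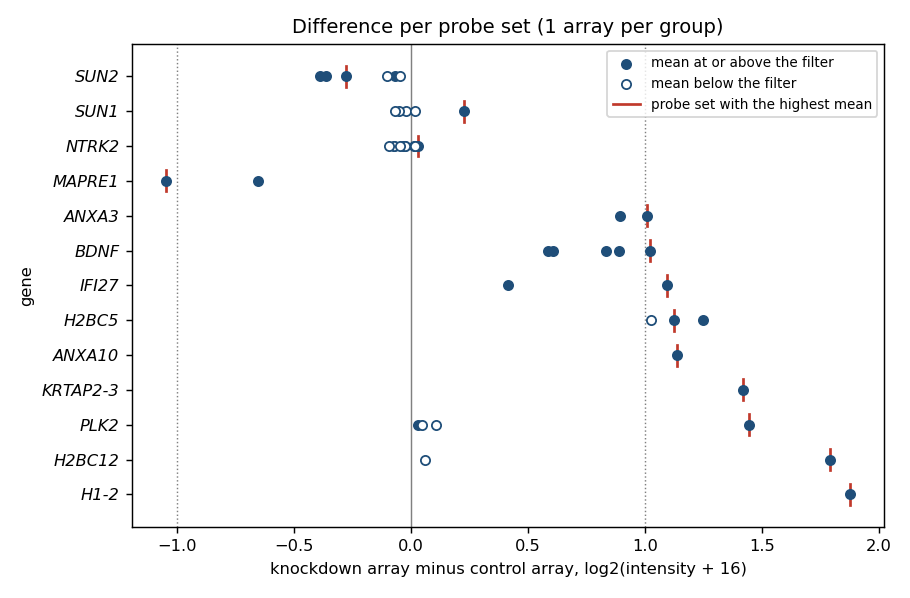
Log2 difference between the knockdown and the control array (x axis, log2(intensity + 16)) for each probe set of SUN2, SUN1, NTRK2 and the 10 genes past 2-fold (y axis); filled points passed the filter, open points did not, the red bar marks the brightest probe set, and dotted lines mark 2-fold. SUN2 probe sets lie between -0.39 and -0.05, far from the -1.05 of MAPRE1.

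Changes of gene groups were small and spread over many members. Of the 41 fixed lists, 8 had a median outside the random range, 4 higher and 4 lower, where 5% of the lists would make about 2.05. The higher lists were interferon-stimulated genes, p53 targets, the TGF-beta pathway and DNA repair. The lower lists were glycolysis, hypoxia targets, immediate early genes and apoptosis regulators. The other 33 lists lay between percentiles 2.57 and 95.5.

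**Figure D2:**
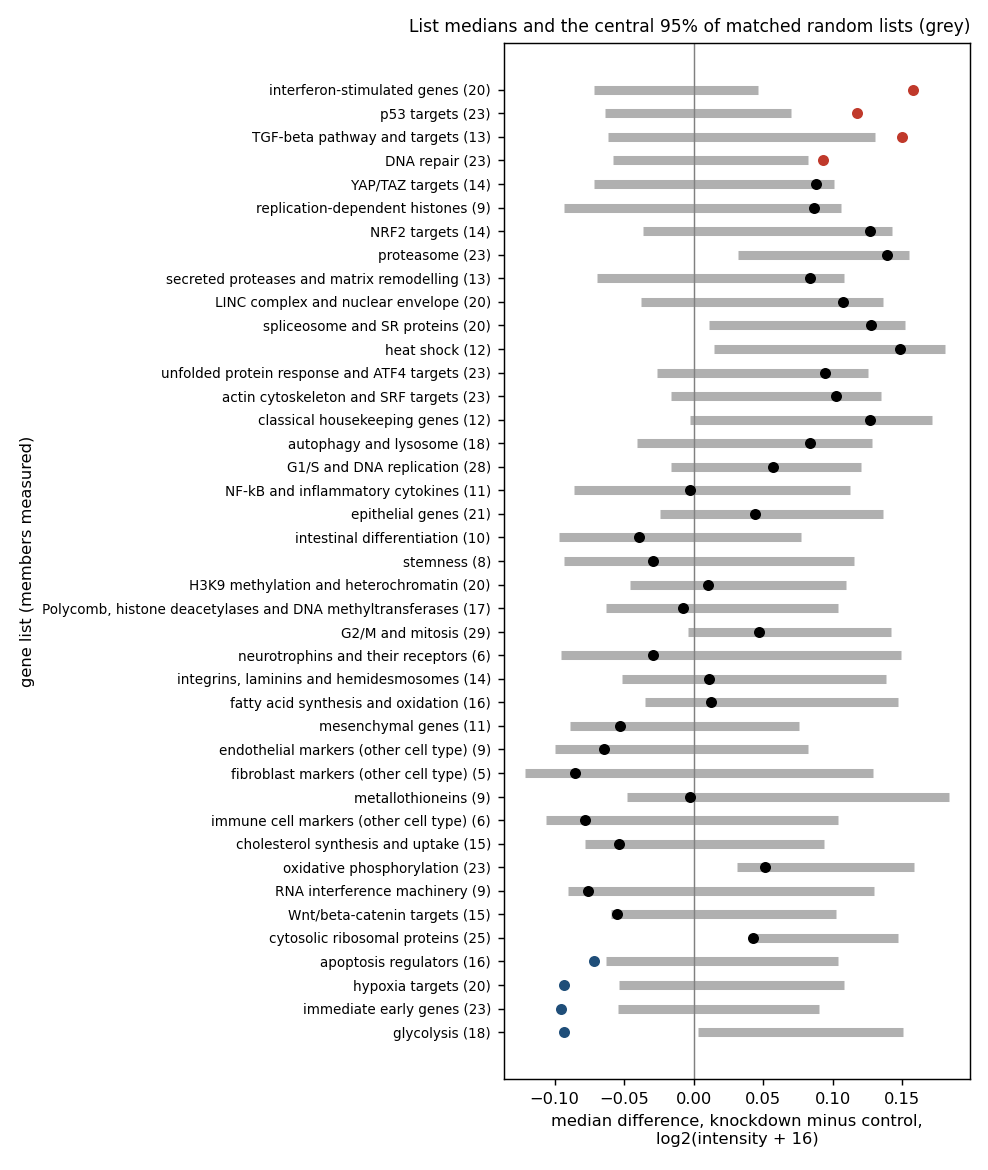
Median log2 difference of each fixed gene list (points, x axis, log2(intensity + 16)) with the central 95% of 10000 random lists matched on mean expression (grey bars); numbers in parentheses are the members measured. Red points (4 lists) lie above their grey bar and blue points (4 lists) below it.

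Interferon-stimulated genes had the highest median of any list, 0.16, above all 10000 random lists, whose median was -0.02. Of the 20 members measured, 16 were higher and 3 of those were at least 1.5-fold higher. IFI27 led at 1.09, followed by IFI6 at 0.93, the ubiquitin-like modifier ISG15 at 0.71 and IFIT1 at 0.45. The last 3 were each measured by 1 probe set past the filter.

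p53 targets were higher as a group, with a median of 0.12 (percentile 99.9) and 20 of 23 members higher. No member reached 1.5-fold. MDM2, the ubiquitin ligase of p53, was higher by 0.39, the cell cycle inhibitor CDKN1A by 0.36, and the death receptors TNFRSF10B and FAS by 0.35 and 0.32. TNFRSF10B had 1 probe set past the filter, of the _x_at class. It stood at 0.13 without the _x_at and _s_at classes, on a probe set below the filter. Both CDKN1A probe sets were higher (0.36 and 0.47), whereas the 7 MDM2 probe sets past the filter ran from -0.07 to 0.39 and the mean over all 11 MDM2 probe sets was 0.04. DNA repair genes had a median of 0.09 (percentile 98.6), with 17 of 23 members higher. XRCC5, a Ku subunit of end joining, was higher by 0.31 on its brightest probe set and differed by -0.04 on the other. Higher values were also found for PARP1 and LIG4, by 0.22 each, and NBN, by 0.21. The DNA repair list fell inside the random range when only genes above the 75th percentile of intensity were kept (percentile 92.7).

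The TGF-beta list had a median of 0.15 (percentile 98.9), with 9 of 13 members higher. The inhibitors of differentiation ID3 and ID2, which BMP signalling also induces, were higher by 0.37 and 0.36, and SMAD3 by 0.26. SMAD3 probe sets disagreed: 2 of the 4 past the filter were lower, to -0.13, and the mean over all 5 was 0.06. SMAD4 was lower (-0.21), and turned to 0.02 when its probe sets were averaged. This list was outside the range under some settings only, and its percentile dropped to 74.9 without the filter on low values.

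Glycolysis genes were lower as a group. Their median was -0.09, below all 10000 random lists, whose median was 0.08, and 12 of 18 members were lower. The aldolases ALDOC and ALDOA differed by -0.55 and -0.27, and glucose-6-phosphate isomerase (GPI) by -0.20. All 5 ALDOC probe sets were lower, by between -0.55 and -0.22. The glucose transporter SLC2A1 went the other way, at 0.50 on its brightest probe set and from 0.08 to 0.50 over its 4 probe sets, with 0.08 on the brightest outside the _x_at and _s_at classes. Without probe sets of the _x_at and _s_at classes, 11 members remained and the list fell inside the random range (percentile 6.49).

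Hypoxia targets had the same median, -0.09 (percentile 0.02), with 15 of 20 members lower. NDRG1 differed by -0.48, ANKRD37 by -0.42 and the peptide hormone ADM by -0.33, while SLC2A1, a member of both lists, was higher. The second NDRG1 probe set past the filter differed by -0.05. ANKRD37 had 1 probe set past the filter and stood at -0.22 when its 2 probe sets were averaged. Averaging the probe sets of each gene put the hypoxia list at percentile 4.72.

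Immediate early genes had a median of -0.10 (percentile 0.02), and 17 of 23 members were lower. The transcription factor EGR1 differed by -0.48, IER3 by -0.45 and the ERK phosphatase DUSP6 by -0.32, while DUSP5 differed by 0.31. All 4 DUSP6 probe sets and all 3 EGR1 probe sets past the filter were lower. Without the _x_at and _s_at classes the percentile was 13.2, with 17 members left. Apoptosis regulators had a median of -0.07 (percentile 1.28) with 11 of 16 members lower. CASP9 differed by -0.21, CFLAR by -0.19 and BAK1 by -0.12, and BIK by 0.38. The list mixes genes that promote apoptosis with genes that restrain it, so its median gives no direction for apoptosis. Both CFLAR probe sets past the filter were lower, and the mean over all 9 was -0.05. The other CASP9 probe set past the filter differed by 0.06, and 1 of 3 BAK1 probe sets by 0.24. That call ended under 5 alternatives, and averaging probe sets turned the list to percentile 71.3. Markers of other cell types were lower by similar amounts, with medians of -0.09 for fibroblast, -0.08 for immune and -0.06 for endothelial markers.

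**Figure D3:**
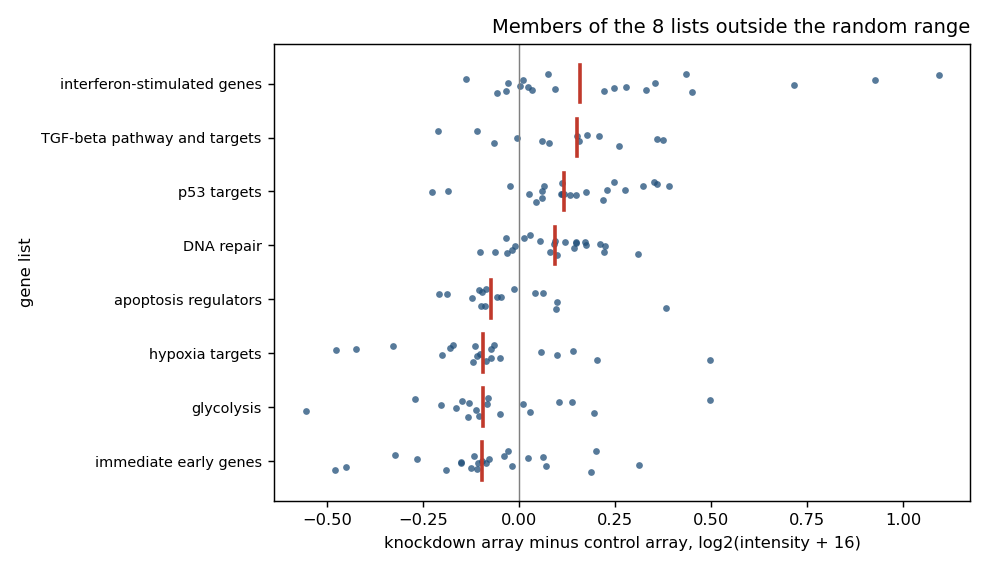
Log2 difference (x axis, log2(intensity + 16)) of each measured member (points) of the 8 lists outside the random range, with the list median as a red bar; vertical scatter within a list carries no meaning. Most members lie within 0.5 of 0, and IFI27, IFI6 and ISG15 stand to the right of the other interferon-stimulated genes.

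The list of LINC complex and nuclear envelope genes did not leave the random range (median 0.11, percentile 91.1), although 15 of 20 members were higher. The 5 lower members were SUN2 itself, the LINC complex genes SYNE2 (-0.25), SYNE1 (-0.19) and SYNE4 (-0.08), and TMEM201 (-0.03). Those other than SUN2 fall outside the naming rule, and only their brightest probe sets are given. Members with increases of similar size included TOR1AIP1 (0.25) and NUP153 (0.23). LMNA, which encodes lamins A and C, was higher by 0.48 on its brightest probe set, with 7 probe sets from -0.03 to 0.48. TMEM43 was higher by 0.41 and TMPO by 0.29, and a second TMPO probe set past the filter differed by -0.04. The neurotrophin list, fixed with BDNF in it, stayed in the random range (percentile 29.2), and BDNF was its only member past 1.5-fold. Mesenchymal and epithelial genes lay at percentiles 19.2 and 40.8. The G1/S and G2/M lists lay at percentiles 57.0 and 31.9. H3K9 methylation genes lay at percentile 35.2. Replication-dependent histones lay at percentile 95.2, and outside the random range under 6 alternatives: H1-2, H2BC12 and H2BC5 were 2-fold higher, H3C4 differed by 0.19, and the 6 members other than those 3 lay between -0.15 and 0.19.

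Intestinal differentiation genes lay at percentile 38.5. Within that list KRT20, a keratin of differentiated colonocytes, was 1.85-fold higher (0.88) and CA2 was higher by 0.25, while ALPI and CEACAM1 differed by -0.15 and -0.11. The 1 KRT20 probe set read 91.1 in the control array, below the filter cut and in the range of the background controls. Its difference was 0.66 with a pseudocount of 64 and 1.18 with normexp. The RNA interference list lay at percentile 5.27, and outside the random range without the _x_at and _s_at classes (0.46) and with the mean of all probe sets (2.30). Its GW182 paralogs went opposite ways: TNRC6A was higher by 0.59, all 4 of its probe sets past the filter between 0.10 and 0.59, and TNRC6B lower, its 8 probe sets between -0.48 and -0.06. XPO5 and TARBP2 differed by -0.18 and -0.16.

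Of 20 markers of other cell types past the filter, 18 were lower in the knockdown array. Fibroblast, immune and endothelial markers lay at percentiles 13.5, 10.98 and 17.0, inside the random range, with 5, 6 and 9 members. Immune markers left that range without the filter on low values (percentile 2.475). The 18 probe sets of the hybridization spike-ins were all higher in the knockdown array, by 0.01 to 0.16 (median 0.09). Of 10 bins of probe sets by intensity, the brightest had a median difference of 0.10 and the fifth one of -0.04. ACTB control probe sets differed by 0.19 at the 3' end and 0.13 at the 5' end, and GAPDH ones by -0.13 and -0.05. The 5' difference minus the 3' difference was -0.07 for ACTB and 0.09 for GAPDH. The 23 background control probe sets were mostly lower in the knockdown array, from 0.01 to -0.33 (median -0.04), with the largest decrease at 25 G or C bases.

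**Figure D4:**
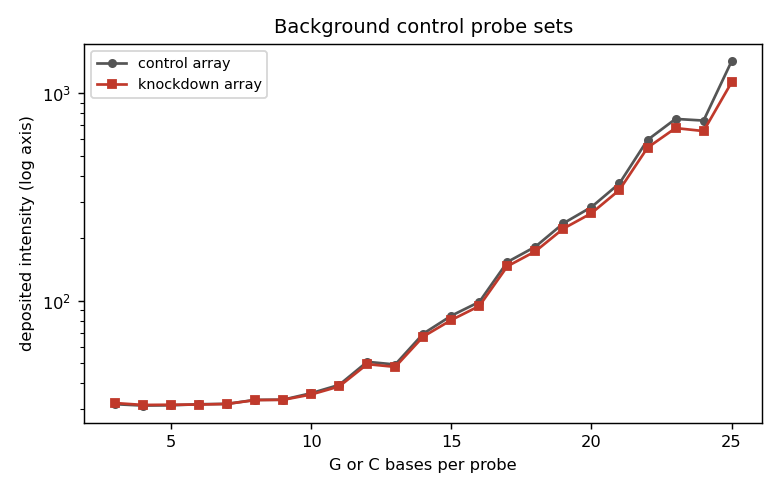
Deposited intensity (y axis, log scale) of the background control probe sets against the number of G or C bases per probe (x axis), for the control array (grey circles) and the knockdown array (red squares). Background rises from about 31.7 to 1425 with GC in the control array and reaches 1128 in the knockdown array.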

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

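The tests in this part were all chosen after the values were seen. Of 2019 probe sets past the filter that the gene comparison leaves out, 2 were at least 2-fold higher in the knockdown array and 0 were 2-fold lower. Both carry 2 gene symbols and so name no gene here. One, of the _s_at class, had an intensity of 87.6 in the control array and 305.9 in the knockdown array (log2 difference 1.64). The other, of the _x_at class, had 578.5 and 1786 (1.60).

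The small SUN2 difference stands beside larger decreases of MAPRE1 (-1.05), HACD2 (-0.82) and TUBA1A (-0.77). Background left in the values could have compressed SUN2. For SUN2 to show the MAPRE1 ratio, itself left uncorrected, a background of 327 would have to be subtracted from both arrays. That is above 18 of the 23 background controls (up to 20 G or C bases) and below the other 5. The GC content of the SUN2 probes is not known here, so this stays open, as do a weak knockdown and a hairpin that acts on further transcripts, neither of which was tested with 1 hairpin.

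H1-2 (1.88), H2BC12 (1.79) and H2BC5 (1.13) were higher in the knockdown array. More labelled RNA without a poly(A) tail is argued against as the whole cause. The highest of the 6 ribosomal RNA control probe sets differed by 0.43 (median 0.25), under the 1.13 of H2BC5. As 5 of these 6 were higher, a smaller contribution stays open. A larger share of cells in S phase is argued against as the whole cause, with a smaller shift and an effect of the knockdown itself untested: the G1/S list lay inside the random range (percentile 57.0), with a median of 0.06 and an upper quartile of 0.14. Probes shared between histone genes stay open for H1-2, which has 0 probe sets outside the _x_at and _s_at classes. H2BC12 and H2BC5 were higher on probe sets outside them (1.79 and 1.25), but these classes come from the array design and probe sequences were not used here.

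For the lower glycolysis and hypoxia lists, a trend of the difference with intensity is argued against. Removing it with loess moved the median differences away from 0, from -0.09 to -0.16 for glycolysis and from -0.09 to -0.11 for hypoxia. This adds no separate support for the lists, since their random lists were already matched on mean expression, with medians of 0.08 and 0.02. Lower non-specific background at high GC stays open for both. Over all measured members the median loss was 32.8 intensity units for glycolysis and 17.7 for hypoxia, below the loss of the background controls from 22 and 20 G or C bases upwards, and the GC content of the probes is not known here. These medians hide larger losses: 7 of 18 glycolysis members lost more than the 81.1 of the control with 24 G or C bases, and 3 (GAPDH, LDHA and ALDOA) more than the 297 at 25, while 6 gained. Of 20 hypoxia members, 2 lost more than 81.1 and 0 more than 297, while 5 gained. Density or oxygen in the culture dish may account for both lists and cannot be told apart from the knockdown with 1 array per group.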

How the results depend on the processing

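No paired analysis was possible because each group holds 1 array, and no array could be left out. The normexp correction was chosen after the values were seen, and all pseudocount settings apply because the values were linear. SUN2 was lower under all 11 alternatives, from -0.36 with quantile normalization to -0.21 with the mean of all probe sets. Not all 11 could have come out otherwise. The 3 other filters leave a gene's value as it is, and a pseudocount cannot change the direction of a probe set. Median centring only took away the median difference of all probe sets, -0.017, and could not change a list's percentile. The interferon-stimulated and p53 lists stayed above the random range under all 11, with lowest percentiles of 99.7 and 98.3. The 9 genes at least 2-fold higher became 6 with quantile normalization, 6 with loess, 4 with the mean of all probe sets, 5 without the _x_at and _s_at classes, 5 with a pseudocount of 64 and 16 with normexp, which kept all 9. The 1 gene 2-fold lower became 0 with the mean of all probe sets and 0 with a pseudocount of 64, and stayed 1 with no filter on low values. At 1.5-fold, the 41 higher genes became 22 with the mean of all probe sets, and the 3 lower genes became 10 with quantile normalization, 8 with loess and 7 with normexp. The share of genes whose probe sets agree in direction was 50.3% without a filter and 75.7% with the 75th percentile filter. Without the _x_at and _s_at classes the lower lists numbered 2: immediate early genes (percentile 13.2), glycolysis (6.49) and apoptosis (2.88) left, hypoxia stayed, and RNA interference machinery entered (0.46), while YAP/TAZ targets (99.5), secreted proteases (97.995) and replication-dependent histones (99.4) entered the higher tail. Apoptosis regulators also left the tail with quantile normalization (4.61), loess (3.77), no filter (3.61) and the 75th percentile filter (15.2), and reversed with the mean of all probe sets (71.3). TGF-beta genes moved to 96.4 with quantile normalization, 97.1 with loess, 89.9 with the mean of all probe sets, 94.9 without the 2 classes and 74.9 with no filter. DNA repair moved to 92.7 with the 75th percentile filter, and hypoxia to 4.72 with the mean of all probe sets. Among the 80 other named genes, 739 values stayed within the probe set SD, 125 moved further and 4 reversed. The 739 include 80 for each of the 3 other filters, which cannot change a gene's own value. They also include 80 for median centring, which shifts every gene alike by less than that SD. Of the 125, 36 moved with the mean of all probe sets. BAK1 (0.044) and SMAD4 (0.016) reversed with the mean of all probe sets. PLAGL1 (-0.082), on 1 probe set below the filter, and TMPO (-0.041) reversed without the 2 classes, where 12 named genes have no value. Lists inside the random range left it in 21 of 348 list and setting pairs, 6 of them for replication-dependent histones and 5 for cytosolic ribosomal proteins, and 15 pairs had fewer than 5 members and gave no value. Apart from the changes in which probe sets or genes were used, the cause was not tested.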

Other observations

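The genes in this part were named after their values were seen. They lie between 1.5-fold and 2-fold, with all probe sets past the filter in 1 direction. The type I keratins KRT23 and KRT13 were higher by 0.91 and 0.64. EZR, which encodes the membrane-cytoskeleton linker ezrin, was higher by 0.65 on its brightest probe set and by 0.57 to 0.99 over its 5 probe sets. The adhesion receptor gene ADGRF1 was higher by 0.74, the growth factor carrier FGFBP1 by 0.84, the cytokine IL18 by 0.80 and the nuclear receptor PPARG by 0.64. KRT23, KRT13, ADGRF1, FGFBP1 and IL18 each had 1 probe set past the filter, and ADGRF1 stood at 0.24 when its 3 probe sets were averaged. FGFBP1 read 86.0 in the control array, below the filter cut and in the range of the background controls. Its difference was 0.62 with a pseudocount of 64 and 1.14 with normexp.

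Signalling and cell cycle genes of this size included BMP4, a secreted morphogen, higher by 0.66 from an intensity of 1184 to 1885. CDK6 was higher by 0.72 and CCNE2, a G1/S cyclin, by 0.80, while the G1/S list as a whole stayed in the random range. The autophagy gene ATG12 was higher by 0.91 on one probe set and by 0.09 on the other. The heparan sulfate enzyme HS3ST1 was likewise uneven, at 0.81 and 0.02. On the lower side, HACD2, an enzyme of very long chain fatty acid synthesis, differed by -0.82 and the alpha-tubulin gene TUBA1A by -0.77 and -0.69 on its 2 probe sets. BMP4, CCNE2 and HACD2 each had 1 probe set past the filter. With the mean of all probe sets HACD2 stood at -0.40, CCNE2 at 0.42 and CDK6 at 0.32. TUBA1A has close paralogs, and both of its probe sets are of the _x_at class.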
